A study of Homo sapiens with 6 samples.

How the data were processed

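RNA from primary human erythroid progenitor cells was measured on 6 single-colour Affymetrix-type expression arrays, 3 from untreated cells and 3 from cells given 0.5 µM SAHA. Per the labels' protocols, CD34-positive cells were driven towards the red cell lineage in a culture of successive steps, total RNA was amplified linearly, and biotin-labelled product was hybridised. The protocols name both bone marrow and cord blood as origins, and which of them each sample had, how long SAHA was present, and whether replicates were separate cultures or donors are not given in the sources used here. The p-values therefore measure only the spread between these arrays, which may be technical.

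The deposited values are probe set intensities. Per the submitters' processing notes they were made with RMA, which corrects background, brings all arrays to a shared distribution and summarises the probes of each probe set; the RMA software, its version and its options are not given in the sources used here. RMA usually gives log2 values, and log2 values had been anticipated. The deposited intensities were linear, so log2 was taken before any test. The table held 22277 probe sets, and its columns all mapped to a sample by their labels. The 62 control probe sets were left out of the tests, leaving 22215. In the platform annotation 19724 of these had 1 gene symbol, 568 had several and 1923 had none. Of the probe sets with 1 symbol, 19707 were matched by gene identifier to the RefSeq table of assembly GRCh38.p14, and 0 symbols needed updating. For 8806 probe sets the annotated transcript was also in that table, and for 43 of them it stood under another symbol; 0 of the genes named by the rule below rested on these. A probe set with several symbols names no gene here. No coordinates are given, because no genome build is stated for the values.

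The comparison of SAHA with untreated was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without a variance trend), with a two-sided moderated test and Benjamini-Hochberg adjustment over all 22215 probe sets at a threshold of 0.05. For genes, the probe set with the highest mean over all 6 arrays stood for each of 12165 genes, and the adjustment was made again over genes. Changes are given as log2 differences, SAHA minus untreated, with the standard error of the moderated fit. Standard errors of differences between sets of genes were instead taken over genes, treated as independent, and do not measure the spread between arrays. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over 29 lists of 3 or more measured members. The lists covered red cell, globin, chromatin, cell cycle, stress and immune genes and markers of other blood cells.

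The lists, the tests and the rule for named genes were fixed before the data were examined. The rule names the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose SAHA arrays all lie outside the untreated range. It always names the measured globin genes, HDAC1, HDAC2, HDAC3, BCL11A, MYB, KLF1, GATA1 and CDKN1A, and 1 further gene that is not reported here. It names up to 4 members of each described list with the smallest unadjusted p. HBG2 and HBM had no probe set of their own symbol alone, so no gene value is given for them.

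The fit was tested on simulated data with the means and spreads of the real probe sets. Among 22215 simulated probe sets, a planted log2 change of 0.5 was called for 30 of 67 (44.8%), a change of 1 for 64 of 67 (95.5%) and a change of 2 for 65 of 66 (98.5%), with 6 calls among unchanged probe sets. A planted shift of 0.3 was called in 2 of 2 lists, with 0 calls among the others; the simulated noise was independent between genes. The number of arrays limits the precision: the median standard error of a log2 change was 0.096 over probe sets.

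The alternatives were the replicate number as a block, median centring, quantile normalization, leaving out the dimmest 40% of probe sets, a variance trend, array weights, each array left out in turn, a 2-fold minimum, no variance moderation, the mean of all probe sets of a gene, camera with an estimated correlation, and fry. Adding 16 to each intensity before log2 was chosen after seeing the data.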

Results

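Gene expression was measured in primary human erythroid progenitor cells, which are immature cells of the red cell lineage grown from CD34-positive blood stem and progenitor cells. Of the 6 arrays, 3 came from untreated cells and 3 from cells given 0.5 µM SAHA (vorinostat), an inhibitor of histone deacetylases, the enzymes that remove acetyl groups from histones and other proteins. Deacetylase inhibitors are studied in such cells because some of them raise fetal globin. The comparison asks which transcripts differ between treated and untreated cells. Median intensity was 59.4, 59.2 and 59.1 on the untreated arrays and 60.4, 60.8 and 60.2 on the SAHA arrays. No pair of arrays was identical. SAHA replicate 1 lay farthest from the other arrays of its group, at a root mean square log2 distance of 0.293, against 0.200 and 0.186 for the other SAHA arrays and 0.167 to 0.203 for the untreated ones.

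Among the genes higher under SAHA was IGFBP5, which encodes a secreted binder of insulin-like growth factors (log2 change 2.10 ± 0.11 SE, limma adjusted p = 0.000714, 3 arrays per group). HES1, a transcriptional repressor downstream of Notch, rose by 1.48 ± 0.24 on the log2 scale, and the immediate early transcription factor gene EGR3 by 1.43 ± 0.09. The embryonic globin gene HBE1 rose 2.71-fold (1.44 ± 0.14). Transcripts of KRT1, a keratin, and CHI3L1, a secreted chitinase-like protein, rose by 1.37 ± 0.17 and 1.35 ± 0.25. The others of the 10 largest rises were CYTIP (1.29 ± 0.15), TIAM1, an exchange factor for the GTPase Rac (1.19 ± 0.10), HPGD, the enzyme that inactivates prostaglandins (1.13 ± 0.12), and LY75, an endocytic receptor (1.13 ± 0.20). Adjusted p over these 10 ran from 0.000714 to 0.0475.

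Among the genes that fell was CA3, a carbonic anhydrase (log2 change −1.53 ± 0.10 SE, limma adjusted p = 0.00147). The water channel gene AQP1, a blood group antigen of red cells, changed by −1.44 ± 0.19, and TRIM10, a gene of terminal erythroid maturation, by −1.37 ± 0.10. ADM, which encodes the vasodilator peptide adrenomedullin, fell as well (−0.95 ± 0.12). So did FGFR3, a fibroblast growth factor receptor (−0.94 ± 0.13), ACHE, acetylcholinesterase (−0.90 ± 0.14), ABCG2, an efflux transporter (−0.89 ± 0.13), and ISG20, an exonuclease induced by interferon (−0.89 ± 0.12). TNXB (−0.94 ± 0.11) and CYP21A2 (−0.93 ± 0.11) overlap each other in the RefSeq table and have near-identical copies nearby, so which of them the probe sets measured is uncertain.

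For 6 of these 20 genes the group with the lower signal lay within the range of 27 bacterial control probe sets, at group means of 3.04 to 4.60 on the log2 scale. Whether those controls were spiked in is not given in the sources used here. The genes were IGFBP5 and CHI3L1 in untreated cells and CA3, AQP1, ADM and ACHE in SAHA-treated cells. Their lower level was not shown to be above background, so their changes are differences of signal whose exact size and rank are uncertain. Several genes also had probe sets that differed from the one used. For IGFBP5, 1 of 5 probe sets changed, and the other 4, also dim, had log2 changes of −0.03 to 0.10. The other FGFR3 probe set was dim and had −0.02. The other TRIM10 probe sets had −0.14, −0.19 and −0.39, the other AQP1 probe set −0.43, and the other ACHE probe set −0.26. The other TIAM1 probe set had 0.35 and did not pass, and 2 of the 5 TNXB probe sets had −0.25 and −0.15 without passing. The other 2 CHI3L1 probe sets had 0.69 and −0.07. HES1 had a second called probe set at 0.90 and a dim one at −0.08.

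**Figure D1:**
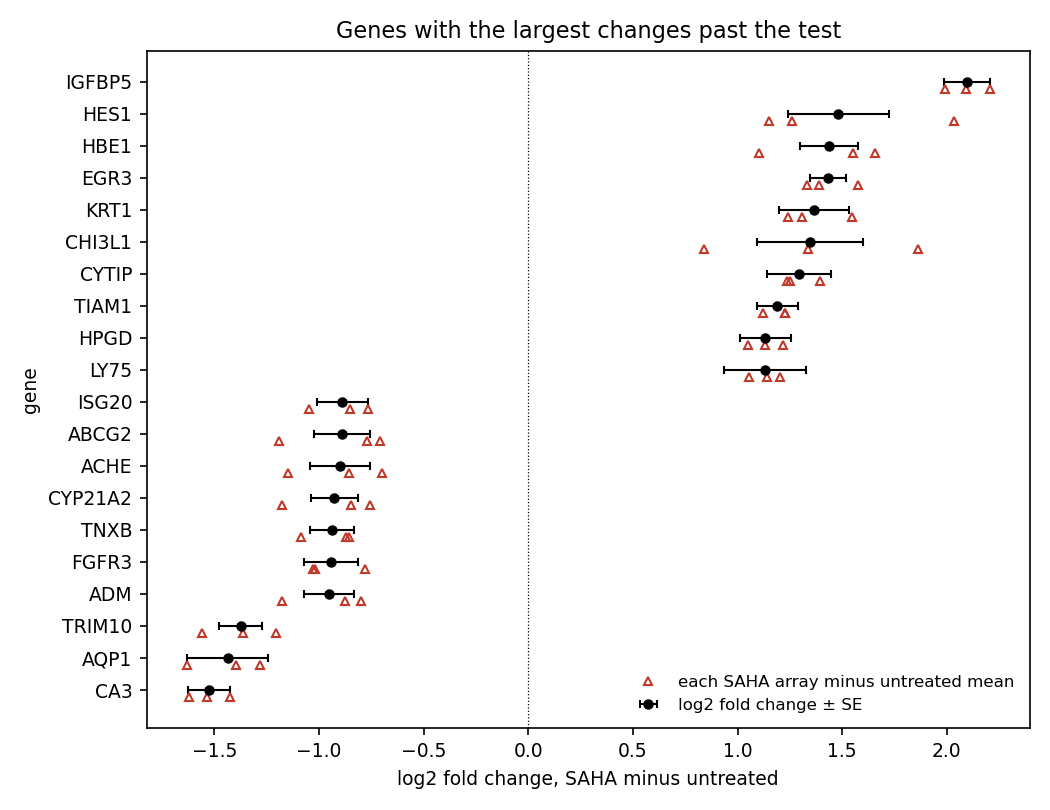
Log2 change, SAHA minus untreated, of the 10 genes with the largest rise and the 10 with the largest fall; black points and bars are the change and its standard error, and triangles are each SAHA array minus the mean of the 3 untreated arrays. The changes run from −1.53 for CA3 to 2.10 for IGFBP5. By the rule that chose these genes, all 3 triangles of each gene lie on the same side of 0.

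In all, 192 of 12165 genes passed, 129 higher and 63 lower in SAHA, and 22 of these changed at least 2-fold (19 higher, 3 lower). Among probe sets 262 of 22215 passed, 166 higher and 96 lower. With each array centred on its median the split was 112 higher and 84 lower genes, and 154 higher and 138 lower probe sets. At an unadjusted p under 0.05 there were 2042 genes (16.8%), and the 3 and 3 arrays did not overlap for 23.9% of genes, against 10% by chance. The gene count depended on which array was left out. It was 56 without untreated replicate 1, 9 without untreated replicate 2, 4 without SAHA replicate 2 and 8 without SAHA replicate 3. Without untreated replicate 3 it was 185, and without the distant SAHA replicate 1 it was 171. The probe set counts moved likewise, to 54, 4, 4, 7, 182 and 194 in the same order. Leaving out an array also reduces the samples, so a lower count alone does not show that a single array carried the changes.

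The globin transcripts moved apart. HBE1, the embryonic beta-like globin gene, rose, whereas the alpha globin genes HBA1 (log2 change −0.86 ± 0.10 SE, limma adjusted p = 0.0139) and HBA2 (−0.44 ± 0.08, adjusted p = 0.0485) fell. Adjusted over probe sets, the 4 probe sets assigned jointly to HBA2 and HBA1 all passed, with a mean of −0.87, a 1.82-fold fall. In that adjustment the HBA1 probe set passed as well (limma adjusted p = 0.0144), and the HBA2 probe set did not (limma adjusted p = 0.0541). Whether the probe sets of HBA1 alone and HBA2 alone tell these genes apart was not tested. Fetal gamma globin was read by 3 probe sets assigned jointly to HBG2 and HBG1. They had a mean log2 change of 0.18, 1.13-fold, with a 95% interval of the averaged value from −0.02 to 0.38, and 0 of the 3 passed (adjusted p 0.271 to 0.421). A dim probe set of HBG1 alone had −0.08. Adult beta globin HBB (−0.11 ± 0.07), delta globin HBD (0.17 ± 0.10), theta globin HBQ1 (−0.30 ± 0.10) and embryonic zeta globin HBZ (−0.28 ± 0.09) did not pass, and a second HBZ probe set had the opposite sign (0.24). Of 8 measured globin genes 1 rose, 2 fell and 5 did not pass; adjusted over the list alone 1 rose and 4 fell. As a set the globins did not pass with camera (adjusted p = 0.176) but passed as lower with fry (adjusted p = 0.0473). The HBB, HBD and joint gamma globin probe sets were among the brightest on the arrays, where the log2 changes of 312 other probe sets also had a small SD, 0.0604.

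**Figure D2:**
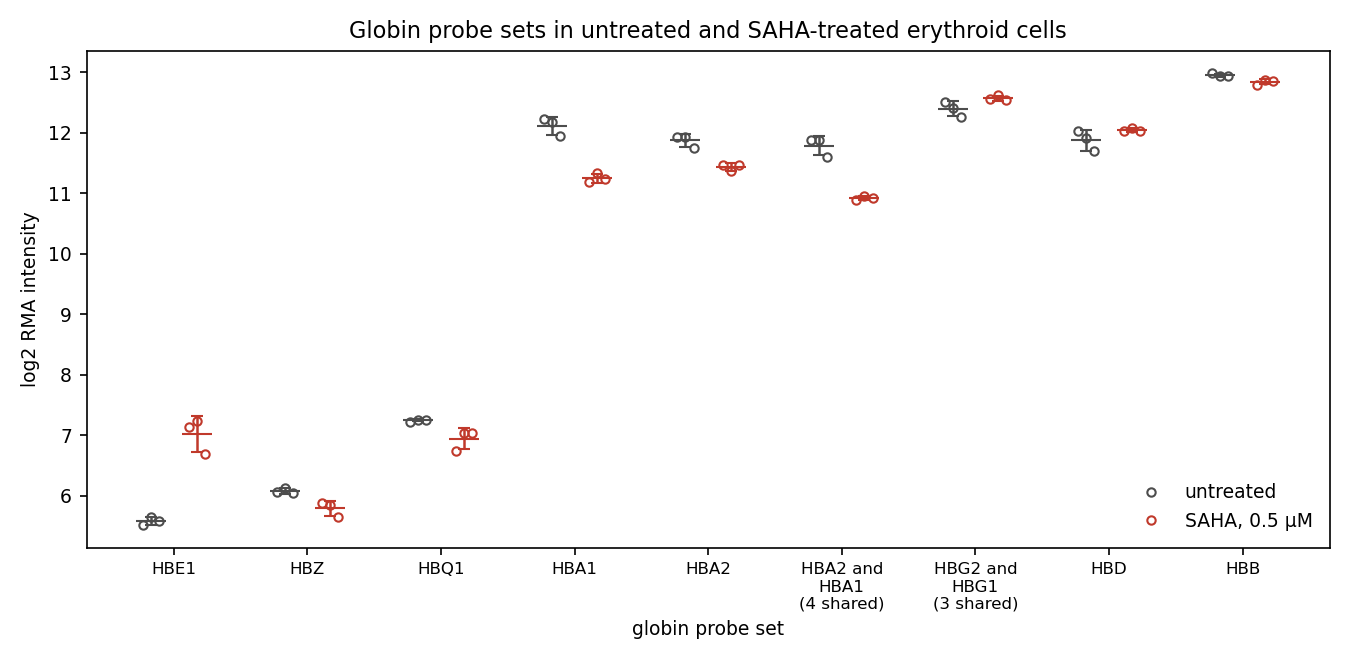
Log2 RMA intensity of the globin probe sets, with a point for each array and the mean and SD of each group of 3; shared probe sets are averaged within an array. HBE1 is higher in SAHA by 1.44, HBA1 lower by a log2 change of −0.86, and the gamma globin probe sets differ by 0.18.

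Genes of the red cell membrane and blood groups were lower under SAHA. All 19 measured members had negative changes, with a median of −0.40 (1.32-fold); 6 fell over all genes tested and 14 adjusted over the list alone. Among them were TSPO2, a membrane protein of late erythroid cells (−0.86), EPB42, protein 4.2 of the membrane skeleton (−0.59), and AQP1 (−1.44) and ACHE (−0.90), both at the level of the bacterial controls in SAHA. The list passed (camera adjusted p = 1.79e-10), with an adjusted p of 0.189 when the correlation was estimated. Of 14 genes of heme synthesis and iron uptake 2 fell, 5 adjusted over the list alone. These 2 were SLC25A37, the mitochondrial iron importer mitoferrin (−0.66), and ALAS2, the first and rate-limiting enzyme of heme synthesis in red cells (−0.61). FECH, which inserts the iron, had −0.32 and did not pass. The list had a median of −0.20 (camera adjusted p = 0.000608), with an adjusted p of 0.293 at an estimated correlation. Among 18 late erythroid enzymes and factors 2 fell, the carbonic anhydrases CA1 (−0.78) and CA2 (−0.43), and 7 adjusted over the list alone; AHSP, the alpha globin chaperone, had −0.39 and SELENBP1 −0.65 without passing. The median was −0.19 (camera adjusted p = 2.07e-05), and the adjusted p with an estimated correlation was 0.189.

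Among the marker lists of other blood cells, the one of monocytes and macrophages passed as higher (camera adjusted p = 0.00135), with VCAN and AIF1 risen, and is described with the histocompatibility genes. Of the other 4 lists 0 passed with camera or with fry, and 2 had an unadjusted camera p under 0.05. The mast cell genes HPGDS, a prostaglandin D synthase (1.02 ± 0.10), and TPSAB1, a tryptase (0.74 ± 0.08), rose, while PRG3, an eosinophil granule protein gene, fell (−0.71 ± 0.10), and CPA3, mast cell carboxypeptidase, had 0.47 without passing. Of the 18 measured granulocyte and mast cell markers 15 did not pass, 3 rose and 1 fell adjusted over the list alone, and the list as a set had a camera adjusted p of 0.083. Of 16 megakaryocyte markers MMRN1 rose (0.49, from the level of the bacterial controls) and 15 did not pass. Adjusted over the list alone 6 rose and 2 fell (camera adjusted p = 0.0537). FLI1, a transcription factor of that lineage, had 0.51. In the alternative settings the megakaryocyte list passed in 8 of 16 and the granulocyte and mast cell list in 3. Of 16 stem and early progenitor markers 0 passed with limma and 5 had an unadjusted p under 0.05, with 1, MEIS1 (0.41), past the test adjusted over the list alone (camera adjusted p = 0.394). Among 19 lymphocyte markers GZMB, the protease granzyme B, rose (0.82) and 18 did not pass; 3 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.971), with a median of −0.02 and a mean of 0.03. The 3' minus 5' log2 difference of the actin control, a sign of RNA quality, was 1.26 on the array of SAHA replicate 1, 1.88 and 1.94 on the other SAHA arrays and 1.84 to 2.07 on the untreated ones.

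Genes of the major histocompatibility complex (MHC), which present peptides to T cells, and of its partners were higher under SAHA. Of the measured members of this list, 13 lie in the MHC region and the others, CD74 among them, lie outside it. All 16 measured members had positive changes, with a median of 0.49 (1.40-fold); 3 rose over all genes tested and 12 adjusted over the list alone. The 3 were HLA-DMA, which loads peptides onto class II molecules (0.96 ± 0.11), the class II invariant chain CD74 (0.69 ± 0.12) and the class II chain HLA-DPA1 (0.71 ± 0.12); the class I gene HLA-B had 0.53 without passing. The list passed (camera adjusted p = 7.54e-13), with an adjusted p of 0.293 at an estimated correlation. Another split of the arrays, with the groups mixed, gave this list an unadjusted camera p of 2.50e-10, against 2.60e-14 for the real split. The size of the p at the preset correlation is therefore not a measure of how sure the rise is. Monocyte and macrophage markers were read beside it. Of 17 measured, VCAN, the proteoglycan versican (0.85), and AIF1, a macrophage actin-binding protein (0.56), rose, and 4 rose adjusted over the list alone. The other AIF1 probe sets had 0.46, 0.49 and, for a dim one, −0.20, and the other VCAN probe sets 0.32 to 0.60, none of them passing. CTSS, cathepsin S, had 0.56 and MS4A6A 0.57 without passing. That list had a median of 0.19 (camera adjusted p = 0.00135), with an adjusted p of 0.565 at an estimated correlation, of 0.335 with fry and of 0.115 without SAHA replicate 2. Another split of the arrays gave it a smaller unadjusted p.

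Both cell cycle lists were lower by small amounts. Of 27 genes of G1/S and DNA replication 2 fell, CCNE1, cyclin E1 (−0.55), and the transcription factor E2F1 (−0.47), and 3 adjusted over the list alone; RRM2, a ribonucleotide reductase subunit, had −0.33. The median was −0.09 (camera adjusted p = 0.00135; adjusted p = 0.293 with an estimated correlation). Of 25 genes of G2/M and mitosis 0 passed over all genes tested with limma, 8 had an unadjusted p under 0.05 and 2 fell adjusted over the list alone. MKI67, the proliferation marker Ki-67, had −0.48, with −0.31, −0.17 and −0.03 for its other probe sets, and DLGAP5 had −0.29. The median of the list was −0.14 (camera adjusted p = 0.000608, and 0.492 with an estimated correlation). Another split of the arrays gave this list a smaller unadjusted p.

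**Figure D3:**
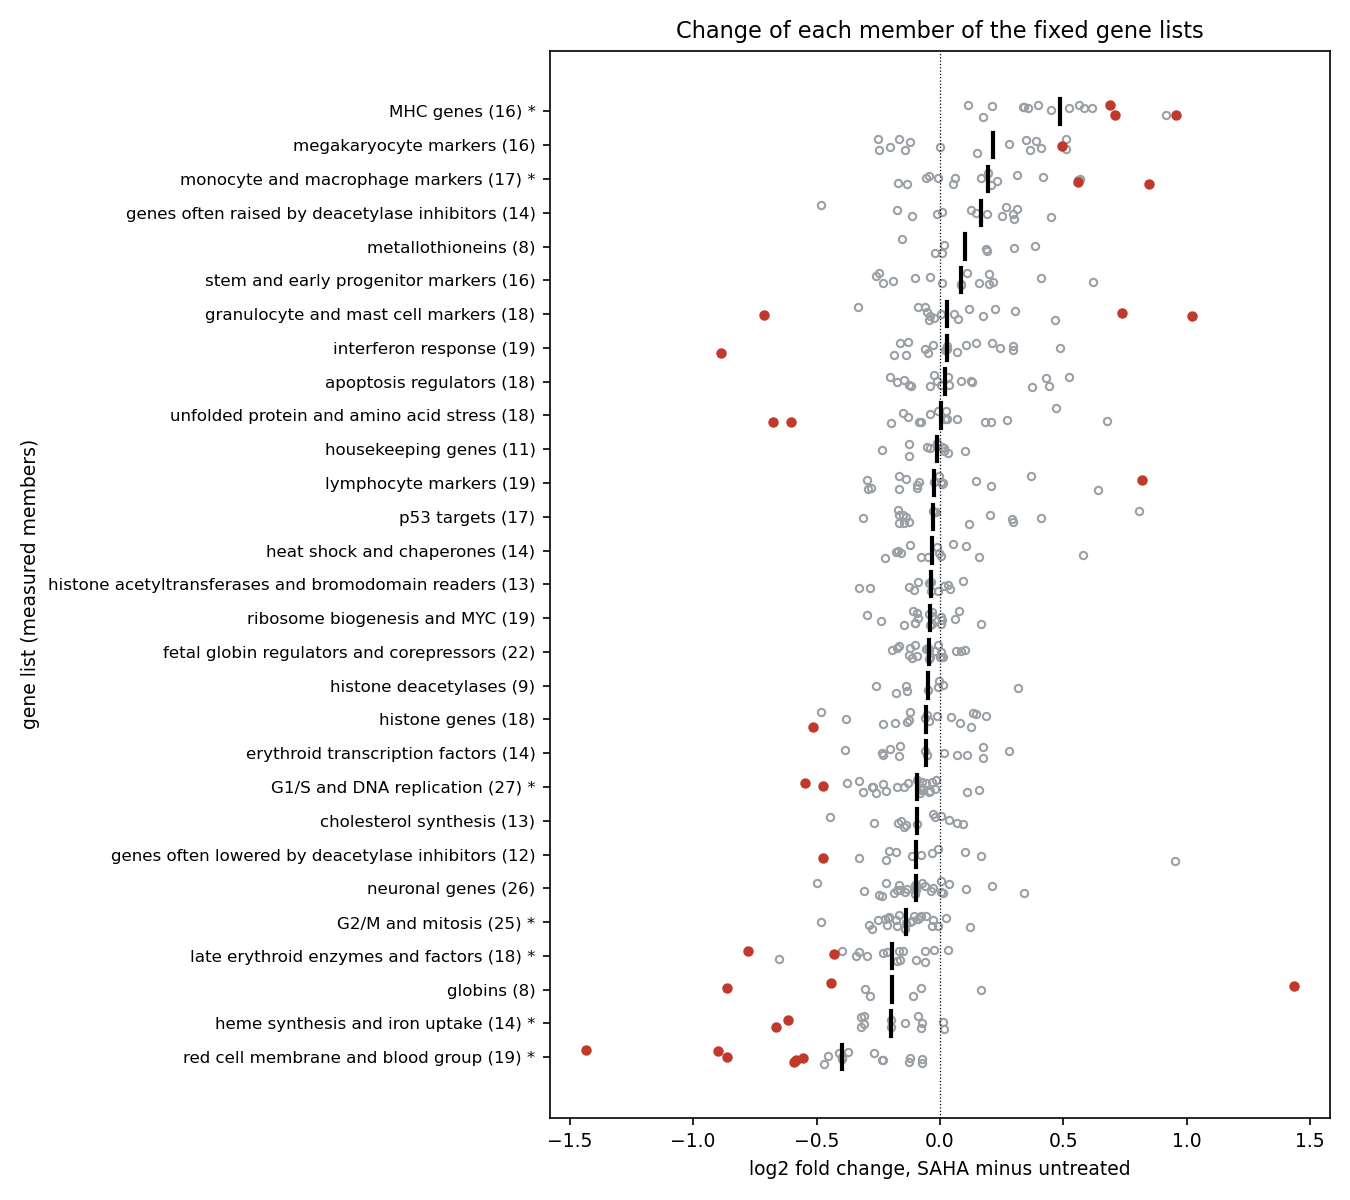
Log2 change, SAHA minus untreated, of each measured member of the 29 gene lists; red filled points are genes past the test over all genes, grey open points are the others, black bars are list medians, numbers in brackets count measured members, and a star marks a list that passed with camera. The MHC list has the highest median, 0.49, and the red cell membrane and blood group list the lowest, −0.40.

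The deacetylases themselves and the known regulators of fetal globin did not pass. HDAC1 had a log2 change of 0.01, HDAC2 −0.01 and HDAC3 −0.14, and 0 of 9 measured deacetylase genes passed with limma, with 3 at an unadjusted p under 0.05 (camera adjusted p = 0.524). BCL11A, a repressor of gamma globin, had −0.11, MYB 0.10, KLF1 −0.17 and GATA1 −0.16. Among 22 fetal globin regulators and corepressors 0 passed and 1 had an unadjusted limma p under 0.05 (camera adjusted p = 0.424). Among 14 erythroid transcription factors these counts were 0 and 3 (camera adjusted p = 0.928). Of 14 genes often raised by deacetylase inhibitors 0 passed over all genes with limma, 4 had an unadjusted p under 0.05 and 1, TXNIP (0.45), rose adjusted over the list alone; CDKN1A, the cell cycle inhibitor p21, had 0.30 ± 0.20 and the histone gene H2BC21 −0.48 (camera adjusted p = 0.0609). Of 12 genes often lowered by such inhibitors E2F1 fell, and CCND1, cyclin D1, had 0.95 without passing (camera adjusted p = 0.344). Adjusted over the list alone 1 rose and 2 fell, and with fry this list passed as lower (adjusted p = 0.0353).

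In the remaining lists few genes passed. The linker histone gene H1-2 fell (−0.52) among 18 histone genes (camera adjusted p = 0.344), and the stress genes ATF3 (−0.61) and CHAC1 (−0.68) fell among 18 genes of the unfolded protein and amino acid stress response (camera adjusted p = 0.971). ISG20 was the 1 interferon response gene of 19 that passed (camera adjusted p = 0.422). Of 26 neuronal genes 0 passed with limma and 4 had an unadjusted p under 0.05, with a median of −0.10 (camera adjusted p = 0.0609). With fry the neuronal list passed as lower (adjusted p = 0.0473). No gene passed with limma in the lists of acetyltransferases and bromodomain readers, ribosome biogenesis, p53 targets, apoptosis regulators, chaperones, metallothioneins, cholesterol synthesis and housekeeping genes. Unadjusted p was under 0.05 for 2, 1, 4, 5, 0, 1, 2 and 0 of their genes, in that order, and the camera adjusted p of these lists ran from 0.217 to 0.971. Adjusted over the list alone 1 apoptosis regulator rose. TNFSF10 of that list had 0.43, and a dimmer probe set of it, at 0.64, passed over probe sets (limma adjusted p = 0.0422). The remaining TNFSF10 probe set had 0.27 without passing. The median, mean and test differed in sign for the p53, chaperone and stress response lists. Of the 29 lists 7 passed with camera, 2 higher and 5 lower; 6 of these also passed with fry and 0 with camera at an estimated correlation, where 2 had an unadjusted p under 0.05.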

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

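Each of the 3 counts of calls was recomputed under the alternatives set for it: no variance moderation was run for probe sets, a 2-fold minimum for probe sets and genes, averaged probe sets for genes and lists, an estimated correlation and fry for lists, and the others for all 3. Adding 16 before log2 was the setting chosen after seeing the data. Among probe sets, 262 as reported, the count was 10 with the replicate block, 406 with dim probe sets left out, 539 with a variance trend, 552 with array weights, 27 with a 2-fold minimum, and 4 to 194 with 1 array left out. With no variance moderation it was 0, against 3540 at an unadjusted limma p under 0.05. Among genes, 192 as reported, it was 53 with the block, 428 with a variance trend, 378 with array weights, 292 (170 higher, 122 lower) with 16 added, 22 with a 2-fold minimum, and 4 to 185 with 1 array left out. A 2-fold minimum is stricter and leaving out an array reduces the samples; for the other settings the cause was not tested. Median centring, quantile normalization and averaged probe sets gave 196, 196 and 217 genes, and 16 added gave 344 probe sets (189 higher, 155 lower). Whether the replicate numbers pair the arrays is not given in the labels. Residuals of same-numbered arrays correlated at 0.032, −0.089 and 0.059, and those of differently numbered arrays at −0.094 to 0.049. No pairing was seen in these values, which cannot exclude it. The count of lists was 7 to 10 under the other settings and 0 with an estimated correlation, where 2 lists had an unadjusted p under 0.05 (9 passed with fry, among them 6 of the 7; the list lost was monocyte and macrophage markers, at an adjusted p of 0.335); the cause was not tested. All 45 named genes past the test kept their sign in every setting run for them. Their 3 and 3 arrays did not overlap, so leaving out an array, array weights, the block or a variance trend could not change the sign. Of these genes 41 were lost without SAHA replicate 2, 38 without SAHA replicate 3 and 37 without untreated replicate 2. The block lost 26, leaving out untreated replicate 1 lost 25, and the other settings lost 0 to 12. Of 94 named genes not past the test, 22 passed in 1 or more settings and 2 changed sign. The median log2 change of all genes was −0.03 as reported and −0.06 with median centring. Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many probe sets and 1 as many genes as the real split (262 and 192, highest other 0), and 3 gave as many lists (7, highest other 9); 10 splits are too few for a share under 0.05. Another split gave a smaller unadjusted camera p than the real one for G2/M and mitosis (1.36e-07 against 0.000105; 2 of 10 splits as small, the real one included) and for monocyte and macrophage markers (5.58e-06 against 0.000317; 4 of 10). The splits with 9 and 8 lists set SAHA replicate 1 with 2 untreated arrays. No detection calls were used here, and 7 of the 43 called genes that the rule names had a group within the range of the bacterial controls.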

Other observations

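A pair of gene families not described above was looked at after the values were seen. Of 16 measured genes of prostaglandin synthesis, breakdown and reception, 4 rose under SAHA, 0 fell and 12 did not pass. Those that rose, with the same sign under each scaling, were HPGDS (1.02 ± 0.10 SE), HPGD (1.13 ± 0.12), the inducible cyclooxygenase gene PTGS2 (0.96 ± 0.14) and the prostaglandin E receptor gene PTGER4 (1.04 ± 0.18), with limma adjusted p from 0.00789 to 0.0374. PTGER4, with 2 probe sets, ran from 0.47 to 1.19 over the alternative settings and passed in 8 of 14. HPGDS and HPGD passed in 12 and PTGS2 in 9. Of 13 measured carbonic anhydrases 3 fell, CA1 (−0.78), CA2 (−0.43) and CA3 (−1.53), with the same sign under each scaling, and 10 did not pass; CA1 and CA2 were bright, and CA3 was at the level of the bacterial controls in SAHA. Of the probe sets annotated to CXCL8, 1 had a log2 change of −1.91 (limma adjusted p = 0.00720), while the others of these 9 did not pass. Which transcript it measured is uncertain, so no value is given for CXCL8. Among the control probe sets, 1 of 18S ribosomal RNA was lower in SAHA (−0.28, limma adjusted p = 0.0377).

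The tests of added mast cell lineage cells, of fewer erythroid cells alone, of the globin genes against a lower erythroid share and of the MHC neighbours were chosen after the results were seen. The mast cell genes TPSAB1 and HPGDS rose, while 10 genes of the 3 red cell lists fell; the granulocyte and mast cell list did not pass (camera adjusted p = 0.083), and the red cell lists had adjusted p of 0.189, 0.293 and 0.189 with an estimated correlation. The mean 3' minus 5' value of the actin and GAPDH controls differed between the groups by −0.178 ± 0.135 SE. With 2 standard errors added this stayed under 0.5, the bound on a difference in RNA integrity set beforehand. With 3 arrays per group that standard error is imprecise, and actin alone had −0.238 ± 0.228, so a difference of 0.5 is not excluded. GAPDH alone was lower in each SAHA array (−0.117 ± 0.050), and SAHA replicate 1 stood at a mean of 0.908 against 1.28 to 1.44 untreated. A lower share of erythroid cells may contribute. Among markers above the median level of all genes, granulocyte and mast cell markers were on average no higher in change than other non-erythroid markers. The difference of mean log2 changes was −0.154 ± 0.122, with the standard error over genes (means 0.126 over 15 genes and 0.280 over 21). Over all measured members the mean was 0.10 for granulocyte and mast cell markers. It was 0.22 for monocyte and macrophage and 0.15 for megakaryocyte markers. Stem and early progenitor markers (0.06) and lymphocyte markers (0.03) moved little. More cells of the mast lineage could contribute too, but the values do not test it. The median was 0.602 over CPA3, TPSAB1, HDC and HPGDS, a set that holds the risen TPSAB1 and HPGDS themselves. CPA3 (0.47) and HDC (0.22) did not pass, and MS4A2, also in the planned set, had no value above the median level. Whether fewer erythroid cells alone account for the red cell genes cannot be told apart from regulation within cells, because the SD of their changes was 2.21 ± 0.24 times their root mean square error over 44 genes, too near the bound of 2, and a change of these genes by SAHA itself stays open.

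HBE1 rose while HBA1 and HBA2 fell. A lower share of erythroid cells would lower HBE1 as well, and its log2 change of 1.44 ± 0.14 SE argues against that explanation for HBE1. It would also lower alpha globin and the other red cell genes by about the same amount. That holds if all of them were read mainly from erythroid cells, which was not tested. HBA1 (−0.863 ± 0.096) lay below the mean of the 44 red cell genes above the median level (−0.290, SD 0.219) by −0.573, and the probe sets shared by HBA2 and HBA1 by −0.576, each over 2 times the spread (0.239 and 0.238, from the SD over genes and the standard error). On that condition the values argue against a lower share as the whole cause of those falls. TSPO2 fell as far (−0.865), however, and a part of the size of the mean stays open. AQP1 (−1.44) and ACHE (−0.90) fell further, but lay below the median level and were not among the 44. The probe set annotated to HBA2 alone lay within the spread of the red cell genes (difference −0.150, spread 0.234). For that probe set a lower share cannot be told apart from regulation. Whether the probe sets of HBA1 alone and HBA2 alone measure these genes separately was not tested, so their difference is not read as one between the genes. A loss of the most mature erythroid cells in particular was not tested. Compression at high signal may hide changes of beta, gamma and delta globin: non-globin probe sets as bright as these had an SD of log2 change 0.492 times (0.398 to 0.608) that of probe sets in the range of the alpha globin ones. This ratio cannot tell compression from bright transcripts that change little. Whether the small difference of the gamma globin probe sets understates a change in transcript stays open. A change of HBE1 and alpha globin under SAHA remains open as a hypothesis.

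All 16 measured genes of the MHC list had positive changes and 3 rose. The list had a camera adjusted p of 0.293 with an estimated correlation. A change shared by the whole chromosome region was not seen in the neighbours compared. These were 46 genes outside the list and above the median level of all genes, without further HLA, MIC, TAP and PSMB genes. Their mean log2 change was −0.09, with 1 called higher and 3 lower, against 0.48 for the 13 listed genes there at any level. The difference was −0.570 ± 0.078, with the standard error over genes. The estimated correlation within the MHC list was 0.679, so that error is likely too small. The marker list of monocytes and macrophages was higher as well (median 0.19, camera adjusted p = 0.00135; 0.565 with an estimated correlation, 0.335 with fry), with VCAN and AIF1 among its risen genes. The mean log2 change of S100A8, S100A9, CD14 and FCN1 lay below that of the class II genes (difference −0.563 ± 0.0999, with the standard error again over genes). As a set these 4 genes rose less than class II, which met the condition set beforehand against added monocytes. It does not decide the question, because other markers of the monocyte and macrophage list had changes near the class II mean of 0.59. These were VCAN (0.85), AIF1 (0.56) and, without passing, CTSS (0.56) and MS4A6A (0.57), while 5 of the 17 measured had negative changes. Of S100A8, S100A9, CD14 and FCN1, 3 were below the median level of all genes, though above the bacterial controls, and S100A8 had 0.23 ± 0.20. Added monocytes stay open. Macrophages or other antigen-presenting cells with little of these transcripts, not tested, and a change by SAHA within the erythroid cells stay open too.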
